A study of Vitis vinifera and Vitis quinquangularis with 24 samples.

How the data were processed

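Skin of grape berries was profiled by RNA sequencing in 2 cultivars at 4 stages with 3 libraries each, 24 libraries, 1 deposited table per library. Per the labels, total RNA was extracted and libraries were made by a standard Illumina protocol. Reads were aligned with TopHat2, per the submitters' processing notes, which give no version. The genome build, the annotation, the program that counted reads and any use of strand are not given in the sources used here. Each table lists 27711 gene models, 27032 with identifiers that begin with VIT and 679 that the identifiers name as newly predicted. Per the file headers, each holds a Count, an FPKM value, a Normalized value and a Length in bp for every model, with its chromosome, start and end.

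The deposited count values are whole numbers that sum to a different total in each library. For 60.8% to 64.9% of the counts above 0, the count equals, within 0.02, the Normalized value divided by 1 factor per library. That factor was the highest ratio of Normalized value to count among models of high count. A further 26.1% to 27.9% lie about 1 above that number, so a part of the counts looks like an estimate that the authors rounded up. The FPKM values were deposited by the authors, per the file headers; how they were computed is not given in the sources used here. The Normalized values are a signal that per the file headers is not otherwise described. They equal the count times 1 factor per library for most models and were used here only in that comparison with the counts. The Length was taken from the deposited tables as given. Counts were the unit of every main test, and FPKM served as an alternative.

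Groups were the cultivar and stage in the labels. The labels do not say whether the 3 libraries of a group came from separate plants or pools, so p-values measure only the spread between these libraries, which may be technical. Total counts ran from 13201295 to 23095568, and 4474 models had 0 counts in all libraries. Bounds of the form at least N-fold set a group of 0 counts to a floor of 3 counts over its 3 libraries; floors and intervals cover counting error only.

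Counts were analysed in R 4.3.3 with edgeR 4.0.16. Models were kept by filterByExpr (18375), libraries were scaled by TMM, and a quasi-likelihood model with 8 groups was fitted to all 24 libraries, which share 1 estimate of the spread; the common biological coefficient of variation was 0.2. A model was called at a Benjamini-Hochberg adjusted p below 0.05 and a change of at least 2-fold. The 13 comparisons were Danfeng-2 against Cabernet Sauvignon at each stage, each successive step and the whole span from E-L 33 to E-L 38 within each cultivar, and the difference of the 2 spans. CPM values are edgeR's counts scaled to the TMM-adjusted library size. Counts were also simulated for all 24 libraries from each model's mean over all groups and its own spread. Of 18375 models, 200 were changed, in Danfeng-2 at E-L 38 only. The edgeR step recovered 89% of 3-fold and 84% of 4-fold changes and called 5 unchanged models. The 27 models it missed had a median coefficient of variation of 0.369, against 0.135 in those it recovered. In the real comparison 5806 models were called, so the simulation does not show how the step performs when many models differ.

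The design, the 13 comparisons, the rule for named genes and the alternatives listed next were fixed before the data were examined. The alternatives were RLE size factors, no filter and a stricter filter on low counts, the replicate number as a block, a fit of the compared groups alone, DESeq2 1.42.0, limma 3.58.1 on log2(FPKM + 1) and log2(FPKM + 0.1), other call thresholds, leaving out models at 0 in 1 species, and leaving out each library in turn. The rule for named genes had 3 parts: members of fixed gene lists, the 5 highest and 5 lowest log2 fold changes among called models with a mean of at least 20 CPM in the higher group and no overlap between libraries, and a set of key genes. The 23 gene lists were written as product names, and the files give none. A RefSeq table of assembly ASM3070453v1 matched 0 of 27711 identifiers. The list tests and the list parts of the rule were therefore not run, and fewer genes are named than planned: the first 2 in each direction for the comparison at E-L 38, the whole span in each cultivar, and the difference of the spans. Identifiers recalled from the literature were looked at and are not used here.

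Chosen after the data were seen were the alternative without the 3 libraries that stood apart, the ripening axis with its thinned libraries, single-cultivar axes and comparison of depth, and the chromosome regions. So were the tests of those 3 libraries for an exchange, reads of the other species or a mixture, and the count of models near 0 in 1 species. For the regions, the tested models of each chromosome were put in order and the number called in the same direction within every 10 consecutive models was compared with the highest number in 10000 random orders, in 14 scans (7 comparisons, 2 directions), after a first run with 1000 orders. This found 32 regions, of which 8, merged into 6, passed 0.05 after multiplication by 14. The orders treat overlapping models that may share reads as separate, so p may be too small where models overlap. The scans were not rerun without such models. The ripening axis is the mean change of log2(CPM + 1) from E-L 33 to E-L 38 over the 3200 models called in the same direction in both cultivars. The same calculation over 15916 models, a wider set than these, gave 0.1, 30.0 and 90.3 on simulated libraries placed at 0, 30.0 and 90.0 percent. Those libraries were made on the axis itself with counting noise only. This checks the arithmetic and not the positions of real libraries, which also lie off the axis.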

Results

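Messenger RNA from berry skin was sequenced in Vitis vinifera cv. Cabernet Sauvignon, a wine grape, and in Vitis quinquangularis accession Danfeng-2, a wild grape of China. Berries were taken at E-L 33, E-L 34, E-L 35 and E-L 38 of the Eichhorn-Lorenz scale, on which they are hard and green, begin to soften, begin to colour and are ripe for harvest. Each of the 8 combinations of cultivar and stage had 3 libraries, 24 in all. Total counts per library ran from 13201295 to 23095568 over 27711 gene models. The title of the series names resveratrol accumulation in the skin as its interest. The files pair no identifier with a gene name and 0 of the 27711 identifiers matched the reference table of names, so genes of the stilbene pathway were not analysed by name here. Genes are therefore given by identifier, and neighbouring genes as chromosome regions in the coordinates of the files, whose genome build is not given in the sources used here.

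Cultivar and stage both separated the libraries. The first principal component held 40.6% of the variance and ran from green to ripe berries in both cultivars, and the second held 28.1% and separated the cultivars. Between partner libraries of a group, the correlation of log2 levels across genes was 0.995 to 0.998 in 18 of 24 pairs. In the other 6 pairs it was 0.941 to 0.973, and each of those pairs held Cabernet Sauvignon E-L 34 replicate 3, Danfeng-2 E-L 33 replicate 1 or Danfeng-2 E-L 35 replicate 1, the 3 libraries that stood apart. The chi-square per degree of freedom of the counts of partner libraries was 1.56 to 4.69 in the former 18 pairs and 73.41 to 164.76 in the other 6. It was at least 1.56 in all 24 pairs, so none was merged as 1 library read again. Part of the counts look like rounded estimates, so this does not measure a difference between berries.

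**Figure D1:**
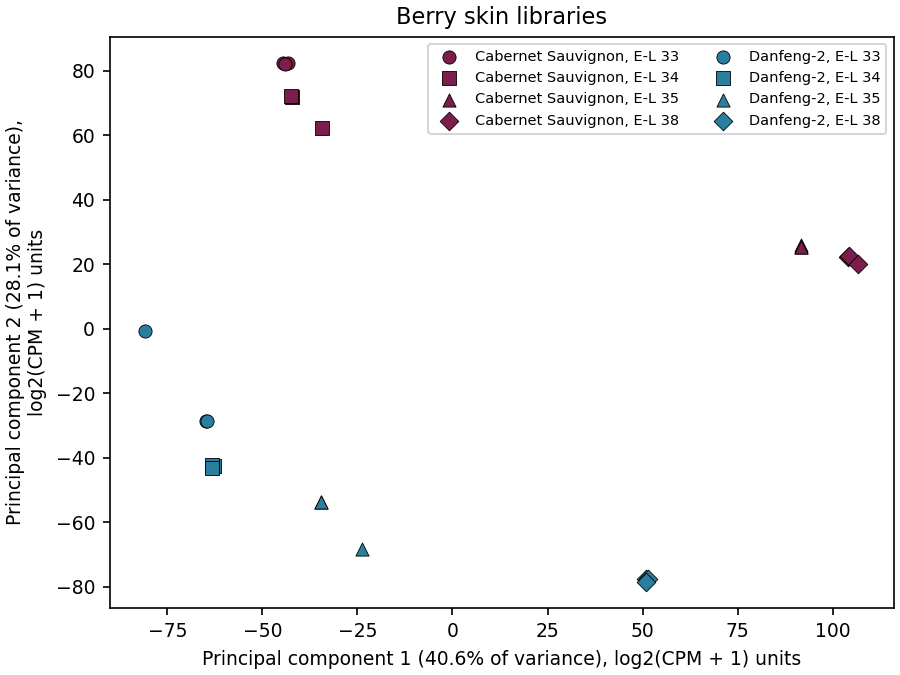
Principal components of log2(CPM + 1) over tested gene models with a mean above 1 CPM, 1 point per library, with colour for the cultivar and shape for the stage. Component 1 (40.6% of the variance) carries the libraries from E-L 33 to E-L 38 in both cultivars and component 2 (28.1%) separates the cultivars.

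The first comparison asked which genes differ between the species at the same berry stage. A region of chromosome 5 from 1938554 to 2163454 was lower in Danfeng-2: 9 of its 9 tested models were called lower at each of the 4 stages (8 at E-L 33 without the 3 libraries that stood apart). Its summed level was 72.8 ± 1.14 CPM (SD, n = 3) in Cabernet Sauvignon and 10.9 ± 1.84 CPM in Danfeng-2 at E-L 33, and 140.4 ± 10.3 against 10.9 ± 0.429 CPM at E-L 38. A region of chromosome 12 from 19036148 to 19514771 went the other way, with 7 of 12 models higher in Danfeng-2 at E-L 33, 10 at E-L 34, 6 at E-L 35 and 7 at E-L 38, and none lower (2 lower at E-L 33 without the 3 libraries that stood apart). Its summed level at E-L 34 was 268.8 ± 3.08 CPM in Danfeng-2 and 123.8 ± 6.44 CPM in Cabernet Sauvignon. In both regions some models overlap one another (5 of 9 and 8 of 12), so reads may be split between them.

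Other regions differed between the species in ways that varied with the stage. On chromosome 13 from 3999388 to 4228520, 16 of 16 models were lower in Danfeng-2 at E-L 34, where the summed level was 111.3 ± 4.36 CPM against 2052.7 ± 339.1 CPM in Cabernet Sauvignon (n = 3 each). At the remaining stages 9 of these 16 models were higher in Danfeng-2, and 4, 5 and 2 were lower at E-L 33, E-L 35 and E-L 38. The large contrast rests on Cabernet Sauvignon at E-L 34, since every other group had a mean between 69.2 and 226.2 CPM. How the berries of that group were sampled or handled cannot be told apart from cultivar and stage in this design. On chromosome 18 from 4982073 to 5171397, 11 of 12 models were higher in Danfeng-2 at E-L 35, with 623.5 ± 30.1 CPM against 135.5 ± 1.21 CPM. Its summed level was also higher in Danfeng-2 at E-L 38 (270.5 ± 4.97 against 129.1 ± 6.67 CPM) and E-L 34 (571.3 ± 42.4 against 377.0 ± 36.8), and at E-L 33 the libraries overlapped (387.5 ± 76.7 against 343.0 ± 15, and 431.8 without Danfeng-2 replicate 1, at 299.0). The models called there were mixed, with 2, 3 and 5 higher and 3, 4 and 3 lower at E-L 33, E-L 34 (5 higher without the 3 libraries that stood apart) and E-L 38. On chromosome 11 from 18903622 to 19019512, 12 of 13 models were higher and 1 was lower in Danfeng-2 at E-L 38, with 705.0 ± 6.69 CPM against 160.4 ± 14.8 CPM. At E-L 33 the same region had 2 models higher (1 without the 3 libraries that stood apart) and 8 lower in Danfeng-2, at 531.1 ± 334.7 CPM against 962.4 ± 5.87 CPM. The Danfeng-2 mean at that stage fell to 338.0 CPM without replicate 1, which stood at 917.3 CPM.

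A region of chromosome 16 from 16197749 to 16725593 held 32 tested models. At E-L 34, 27 of them were higher in Danfeng-2 and none lower, with 603.8 ± 9.0 CPM against 78.8 ± 14.3 CPM. At E-L 38, 18 were lower in Danfeng-2 and 3 higher (5 without the 3 libraries that stood apart), with 498.6 ± 9.8 CPM against 1125.1 ± 130.7 CPM. Of these models 23 overlap another, so the split of reads among them is uncertain and their number is not a number of independent genes. The regions were found by a scan of all chromosomes made after the data were seen. In a permutation test against 10000 random orders of the models, p multiplied by the 14 scans was 0.0014 on chromosomes 11 (at E-L 38) and 16 (at E-L 34), 0.0028 on 13, 0.0042 on 18, 0.0154 on 12 and 0.0392 on 5 (both at E-L 34). The chromosome 5 region did not pass 0.05 at E-L 33 (0.0616), E-L 35 (0.1190) and E-L 38 (0.1092), nor did the lower models of chromosome 16 at E-L 38 (0.1092). The smallest p that the orders can give is 0.0001 before that multiplication. Random orders separate overlapping models, which may be called together because they share reads. The p-values of the scans, here and below, may therefore be too small where models overlap, as on chromosomes 5, 12, 13, 16 and 18. The scans were not rerun without overlapping models, so the size of this effect is not known.

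**Figure D2:**
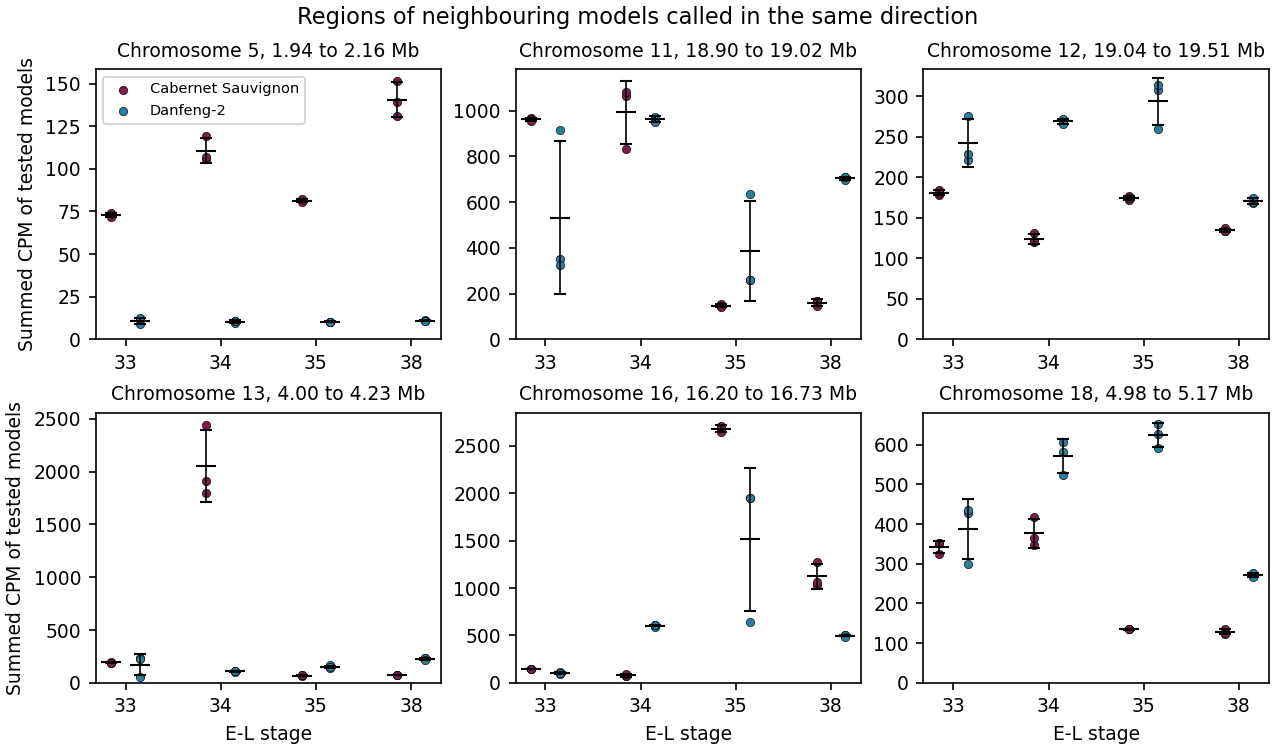
Summed CPM of the tested models in each of 6 chromosome regions against E-L stage, 1 point per library, with the mean and SD of 3 libraries. At E-L 34 the chromosome 13 region stands at 2052.7 CPM in Cabernet Sauvignon and 111.3 CPM in Danfeng-2, and the chromosome 16 region at 78.8 and 603.8 CPM.

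Single genes reached larger contrasts in ripe skin. VIT_05s0077g00170 on chromosome 5, from 86857 to 173741, had 84.7 ± 2.06 CPM in Danfeng-2 at E-L 38 and 0 counts in the 3 Cabernet Sauvignon libraries, at least 1152.9-fold higher against a floor of 3 counts over the group. It was read in Danfeng-2 at all 4 stages, from 59.4 ± 5.32 to 84.7 ± 2.06 CPM. VIT_18s0001g12810 (chromosome 18, from 10917869 to 10933193) had 79.1 ± 2.24 CPM in Danfeng-2 at E-L 38, at least 1076.5-fold higher, and 0.441 ± 0.326 CPM in Danfeng-2 at E-L 33. VIT_06s0009g02830 (chromosome 6, from 15714613 to 15715979) had 421.8 ± 55.9 CPM in Cabernet Sauvignon and 0 counts in Danfeng-2 at E-L 38, at least 5358.9-fold lower in Danfeng-2. VIT_03s0017g00870 (chromosome 3, from 16023963 to 16025246) had 280.1 ± 20.7 CPM in Cabernet Sauvignon and was at least 3559.2-fold lower in Danfeng-2, with 0 counts. The Benjamini-Hochberg adjusted p from edgeR's quasi-likelihood test was 2.6e-13, 1.1e-06, 1.5e-13 and 1.8e-14 for these models in that order.

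Across the genome, 5173 of 18375 tested models (28.2%) were called between the cultivars at E-L 33, 2482 higher and 2691 lower in Danfeng-2. The numbers were 5041 at E-L 34 (2355 higher, 2686 lower), 6321 at E-L 35 (3248 higher, 3073 lower) and 5806 at E-L 38 (2810 higher, 2996 lower). Which direction held more models turned at E-L 33 without a fold minimum, at E-L 35 without Danfeng-2 replicate 1 (3086 higher, 3232 lower) and at E-L 38 with limma or a fit of the 2 groups alone. At all 4 stages 689 models were higher in Danfeng-2, where 8.6 would fall together if the stages' lists were independent, and 849 were lower, against 10.7. A further 1242 models were higher at one stage and lower at another. The fold changes between cultivars correlated between stages with r = 0.54 to 0.70 across models, which are not independent replicates. The libraries of the 2 groups did not overlap for 62.8% to 77.1% of all tested models, where chance gives 10%, and for 95.2% to 99.0% of the called ones, which the calling itself favours. The reference that the reads were aligned to is not named in the sources used here. Every library's table lists the same models at the same coordinates, so both species were counted on a common reference. If that was Vitis vinifera, a lower count in Danfeng-2 can also come from reads that did not align, the chromosome 5 region included.

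**Figure D3:**
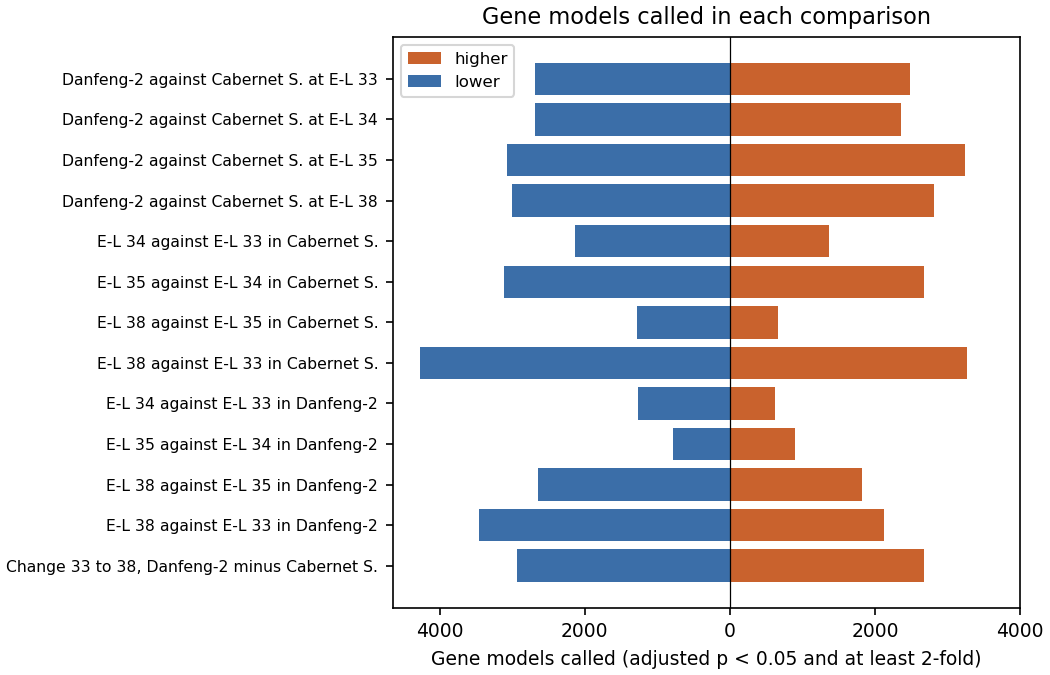
Gene models called in each comparison (adjusted p below 0.05 and at least 2-fold), higher to the right and lower to the left. The counts run from 1676 models for E-L 35 against E-L 34 in Danfeng-2 to 7537 for E-L 38 against E-L 33 in Cabernet Sauvignon.

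The second comparison followed ripening in Cabernet Sauvignon. VIT_01s0011g05110 on chromosome 1, from 4747570 to 4775700, had 1.05 ± 1.82 CPM at E-L 33 and 4858.7 ± 564.1 CPM at E-L 38 (n = 3 each), a ratio of 4629.9, and its 56 counts at E-L 33 all came from replicate 2. VIT_00s0225g00230, on no assigned chromosome, had 0 counts at E-L 33 and 34, 89.7 ± 1.5 CPM at E-L 35 and 52.5 ± 4.03 CPM at E-L 38, at least 824.6-fold higher at E-L 38 than at E-L 33. VIT_14s0068g00140 (chromosome 14, from 23848301 to 23848892) had 57.7 ± 0.508 CPM at E-L 33, 20.3 ± 5.04 at E-L 34 and 0 counts at E-L 38, at least 786.1-fold lower. VIT_18s0001g06690 (chromosome 18, from 5029717 to 5032277) had 52.8 ± 3.12 CPM at E-L 33, 75.4 ± 25.1 at E-L 34 and 0 counts at E-L 38, at least 718.7-fold lower. It lies within the chromosome 18 region, in which 8 of 12 models fell and none rose from E-L 33 to E-L 38. Their Benjamini-Hochberg adjusted p from edgeR was 9.2e-10, 1.1e-11, 1.9e-09 and 1.2e-07 in that order.

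The chromosome 16 region had 148.0 ± 1.6 CPM at E-L 33 in Cabernet Sauvignon, 78.8 ± 14.3 at E-L 34, 2678.6 ± 36.5 at E-L 35 and 1125.1 ± 130.7 at E-L 38. Of its 32 models 24 fell and 1 rose from E-L 33 to E-L 34, 27 rose and 1 fell from E-L 34 to E-L 35, and 16 fell and none rose from E-L 35 to E-L 38. Over the whole span the scan found a rise of 27 of 30 models from 16197749 to 16711898 (permutation p multiplied by 14 of 0.0084). The chromosome 13 region had 193.6 ± 2.7 CPM at E-L 33, 2052.7 ± 339.1 at E-L 34 and 69.2 ± 1.39 at E-L 35, with 10 of 16 models rising on the first step and 13 falling on the next. The chromosome 11 region had 962.4 ± 5.87 CPM at E-L 33 and 992.5 ± 139.0 at E-L 34, then 146.0 ± 6.13 at E-L 35.

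From E-L 33 to E-L 38, 3268 models rose and 4269 fell in Cabernet Sauvignon, 7537 of 18375 tested (41%). By single steps, 3492 were called from E-L 33 to 34 (1363 rose, 2129 fell), 5776 from E-L 34 to 35 (2670 rose, 3106 fell) and 1950 from E-L 35 to 38 (667 rose, 1283 fell). Without a fold minimum more models rose than fell on the first step (4412 and 4230) and on the next (5608 and 5394). For 54.6% of the models that rose over the whole span and 51.2% of those that fell, the largest step was that from E-L 34 to 35. The count for the last step was 1218 with limma on log2(FPKM + 1).

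The third comparison followed the same stages in Danfeng-2. VIT_06s0009g03120 (chromosome 6, from 16266089 to 16268195) had 0 counts at E-L 33, 0.128 ± 0.222 CPM at E-L 35 and 326.9 ± 1.75 CPM at E-L 38, at least 6185.0-fold higher than at E-L 33. It lies at the end of the chromosome 6 stretch given above for the comparison of the species. VIT_08s0007g08330 (chromosome 8, from 21672949 to 21675667) had 0 counts at E-L 33 and 78.7 ± 3.76 CPM at E-L 38, at least 1489.4-fold higher. VIT_06s0080g00760 (chromosome 6, from 20755134 to 20756190) had 738.5 ± 1068.9 CPM at E-L 33 and 0 counts at E-L 38, at least 9382.7-fold lower, a bound that became 1542.0 without replicate 1 of E-L 33. That library held 1972.8 CPM of it and its partners 119.3 and 123.4 CPM. The newly predicted model Grape_newGene_1381 (chromosome 4, from 14427690 to 14430563) was also called lower, but replicate 1 of E-L 33 held 1066.3 CPM of it and its partners 0.0504 and 0.143 CPM. The Benjamini-Hochberg adjusted p from edgeR was 1.6e-11, 4.8e-09, 7.9e-06 and 0.0081 in that order, and for Grape_newGene_1381 it became 0.14 when the 2 compared groups alone were fitted.

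The chromosome 16 region had 102.7 ± 10.4 CPM at E-L 33 in Danfeng-2, 603.8 ± 9.0 at E-L 34, 1513.2 ± 753.0 at E-L 35 and 498.6 ± 9.8 at E-L 38. At E-L 35 replicate 1 had 643.7 CPM and the mean of its partners was 1947.9 CPM. From E-L 33 to 34, 26 of its 32 models rose and none fell, 12 rose on the next step (24 without the 3 libraries that stood apart) and 21 fell from E-L 35 to 38. As in Cabernet Sauvignon, the scan of the whole span found a rise there. It covered 22 of 24 models from 16238965 to 16684265 (permutation p multiplied by 14 of 0.0014). The chromosome 13 region had 172.5 ± 98.5 CPM at E-L 33 (229.3 without replicate 1), 111.3 ± 4.36 at E-L 34 and 226.2 ± 9.94 at E-L 38. The chromosome 11 region had 531.1 ± 334.7 CPM at E-L 33, 964.6 ± 12.8 at E-L 34, 385.2 ± 217.8 at E-L 35 and 705.0 ± 6.69 at E-L 38. Without replicate 1 the means at E-L 33 and E-L 35 were 338.0 and 259.5 CPM. Without the 3 libraries that stood apart, 12 of its 13 models rose and none fell from E-L 33 to 34. On the next step 1 rose and 11 fell. From E-L 33 to E-L 38, 9 of the 13 models rose and 3 fell. The scan for that rise did not pass 0.05 (permutation p multiplied by 14 of 0.2422), nor did that for the fall in Cabernet Sauvignon (0.1022).

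From E-L 33 to E-L 38, 2121 models rose and 3462 fell in Danfeng-2, 5583 in all (30.4%). By single steps, 1893 were called from E-L 33 to 34 (622 rose, 1271 fell), 1676 from E-L 34 to 35 (892 rose, 784 fell) and 4470 from E-L 35 to 38 (1822 rose, 2648 fell). The largest step was the last one, from E-L 35 to 38, for 64.4% of the models that rose over the whole span and 65.0% of those that fell. Which direction held more models on the step from E-L 34 to 35 turned in 5 of 17 alternatives, among them 490 rising and 689 falling with limma on log2(FPKM + 1), 1154 and 1300 without the 3 libraries that stood apart, and 1004 and 1051 without Danfeng-2 E-L 35 replicate 1. The first step gave 939 calls (438 rose, 501 fell) when the 2 compared groups alone were fitted and 1140 with limma on log2(FPKM + 1).

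The changes over the whole span overlapped between the cultivars. In both, 1087 models rose, where 377.2 would be shared by independent lists, and 2113 fell, against 804.3. Another 166 rose in Cabernet Sauvignon and fell in Danfeng-2, and 200 did the reverse, against 615.7 and 492.8. The fold changes correlated with r = 0.55 across models. On an axis through the 3200 models called in the same direction in both, with each cultivar's own E-L 33 mean at 0 and its E-L 38 mean at 100, E-L 34 lay at 17.3% ± 2.2 (SD, n = 3) in Cabernet Sauvignon and 17.2% ± 0.2 in Danfeng-2 (16% and 12.6% without the 3 libraries that stood apart). At E-L 35 Cabernet Sauvignon lay at 88.0% ± 0.1 and Danfeng-2 at 38.3% ± 8.1 (29.2% without them), a gap of 49.7 percentage points. No library of either cultivar overlapped the other there (two-sided exact permutation p = 0.1, n = 3 each, the smallest p that 3 against 3 can give). The axis was chosen after the data were seen.

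**Figure D4:**
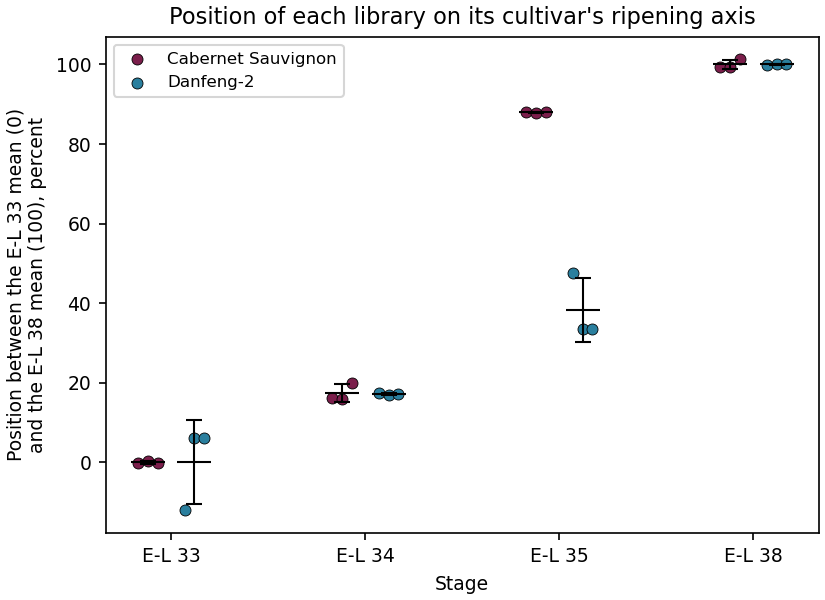
Position of each library on its cultivar's ripening axis (percent, 0 at the cultivar's E-L 33 mean and 100 at its E-L 38 mean) against stage, with the mean and SD of 3 libraries. At E-L 35 the Cabernet Sauvignon libraries lie between 87.8% and 88.0% and the Danfeng-2 libraries between 33.6% and 47.6%.

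The last comparison tested whether the change from E-L 33 to E-L 38 differed between the cultivars. On chromosome 11, 10 of the 13 models of the region changed more positively in Danfeng-2 and 1 more negatively (2 without the 3 libraries that stood apart). In the permutation scan of this comparison the region did not pass (p multiplied by 14 of 0.0532). Its summed level was 962.4 and 160.4 CPM at the 2 stages in Cabernet Sauvignon, and 531.1 (338.0 without replicate 1) and 705.0 CPM in Danfeng-2. At E-L 34, between these stages, it was 992.5 ± 139.0 CPM in Cabernet Sauvignon and 964.6 ± 12.8 CPM in Danfeng-2. VIT_04s0079g00690 (chromosome 4, from 11505001 to 11507285) had 0.739 ± 0.876 CPM at E-L 33 and 2929.4 ± 145.8 CPM at E-L 38 in Cabernet Sauvignon, and 0.473 ± 0.414 (0.71 without replicate 1) and 0.206 ± 0.11 CPM in Danfeng-2 (difference of log2 changes -13.08, SE 1.16, adjusted p = 9.2e-08 by edgeR). At E-L 33 in Cabernet Sauvignon replicate 2 had 1.74 CPM of it and its partners 0.341 and 0.133. VIT_18s0001g01300 (chromosome 18, from 1877187 to 1968096) had 80.8 ± 2.93 and 0.0497 ± 0.0861 CPM in Cabernet Sauvignon, and 9.61 ± 3.23 and 11.3 ± 0.722 CPM in Danfeng-2 (10.72, SE 1.68, adjusted p = 3.2e-05 by edgeR). Its 2 counts at E-L 38 in Cabernet Sauvignon both came from replicate 3. VIT_01s0026g02330 (chromosome 1, from 11816126 to 11817819) went from 34.0 ± 1.3 CPM to 0 counts in Cabernet Sauvignon, and had 0.79 ± 1.2 (0.0995 without replicate 1, at 2.17) and 1.36 ± 0.616 CPM in Danfeng-2 (adjusted p = 2.6e-05 by edgeR). VIT_06s0009g03000 (chromosome 6, from 16048244 to 16048721) went from 0 counts to 30.9 ± 1.75 CPM in Cabernet Sauvignon, while the 6 Danfeng-2 libraries held 1 count (adjusted p = 0.0039 by edgeR, and 1.0 without the library with that count, Danfeng-2 E-L 33 replicate 3).

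The difference was called for 5614 models, 2676 with a more positive and 2938 with a more negative change in Danfeng-2. Which of these held more models turned in 6 of 23 alternatives, among them 2821 and 2722 with RLE size factors, 2875 and 2785 with DESeq2, and 3412 and 3206 without the 3 libraries that stood apart. Of the former, 1163 fell in Cabernet Sauvignon and were not called in Danfeng-2, 492 rose in Danfeng-2 and were not called in Cabernet Sauvignon, and 200 fell in Cabernet Sauvignon and rose in Danfeng-2. Of the latter, 1206 rose in Cabernet Sauvignon and were not called in Danfeng-2, 618 fell in Danfeng-2 and were not called in Cabernet Sauvignon, and 166 rose in Cabernet Sauvignon and fell in Danfeng-2. The median difference over all tested models was -0.11 on the log2 scale, and -0.06 with another scaling of the libraries. A loss of the same share of reads at both stages drops out of this comparison only for models still read in Danfeng-2. A complete loss would not drop out. A model almost unread in Danfeng-2 at both stages differs wherever Cabernet Sauvignon changed, as VIT_06s0009g03000 and VIT_04s0079g00690 did. The former lies in the chromosome 6 stretch that also holds VIT_06s0009g02830 and VIT_06s0009g03120, so these models may not be independent.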

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

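The tests for an exchanged library, reads of the other species, a mixture of samples and lost Danfeng-2 reads were chosen only after the results they bear on were seen, as were the added check of the ripening axis on shared models and the comparison of depth at E-L 34 and E-L 35.

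The change from E-L 33 to E-L 38 differed between the cultivars for 5614 models by edgeR's test of the difference itself. When the 12 libraries of those groups were fitted alone, 5521 models were called. Only the real one of 41 splits of the libraries gave as many (1 of 41, highest other 3220, median of the others 0). The other splits mix the cultivars within a group, so the difference between cultivars widens their spread and lowers their calls. They therefore cannot show whether chance alone would give as many. The named models differed by 12.99 (VIT_01s0026g02330), 10.72 (VIT_18s0001g01300), -13.69 (VIT_06s0009g03000) and -13.08 (VIT_04s0079g00690) on the log2 scale. The fitted values of VIT_01s0026g02330 and VIT_06s0009g03000 rest on groups with 0 counts and are no bounds. In the chromosome 11 region 10 models changed more positively in Danfeng-2 and 1 more negatively, and the permutation scan of this comparison (10000 orders) did not pass 0.05 (p multiplied by 14 scans of 0.0532). For the 12 comparisons of 2 groups, the 10 splits of 6 libraries are too few for a share under 0.05; the real split (1 of 10) gave between 939 and 7723 calls and the highest other split gave 0.

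In 3 groups, Cabernet Sauvignon E-L 34 and Danfeng-2 E-L 33 and E-L 35, 1 library stood apart from its partners. An exchange with another group is argued against by the correlation with the nearest other group, at most 0.952, while partners elsewhere reach 0.995; but Danfeng-2 E-L 35 replicate 1, which gave 0.952 with Danfeng-2 E-L 34, was no closer to its own partners (0.951), and the best mixture gave its own group a weight of 39%. Reads of the other species are argued against by its marker models, at a median of at most 0.39% of that species' level. A mixture of the series' own samples is argued against by the smallest misfit of the best mixture, a root mean square of 0.47 log2 units. Partner libraries elsewhere differed by 0.16 to 0.23. The library with 0.47, Cabernet Sauvignon E-L 34 replicate 3, differed from its own partners by 0.56. A shift along the straight line from E-L 33 to E-L 38, ahead or behind, accounts for at most 11.7% of the squared deviation. On the ripening axis Danfeng-2 E-L 35 replicate 1 lay at 47.6% (partners 33.6%) and E-L 33 replicate 1 at -12.1% (partners 6.0% and 6.1%). Cabernet Sauvignon E-L 34 replicate 3 lay at 19.9% (partners 16.1% and 15.9%). Ripening changes that do not follow that line escape this test. What stays open is a difference in ripening off that line, and any other difference between these berries or their handling, which was not tested. No biological explanation for a single library is given by the design.

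Models near 0 (below 0.1 CPM in all groups) in Danfeng-2 and at 5 CPM or more in Cabernet Sauvignon numbered 110, and the reverse 47, a ratio of 2.34 (exact 95% interval 1.65 to 3.37). The ratio was 1.59 (1.32 to 1.92) at 1 CPM or more and 5.0 (2.31 to 12.37) at 20, while models at 0 counts in all libraries of a cultivar went the other way, 5427 in Danfeng-2 and 5727 in Cabernet Sauvignon. Whether Danfeng-2 reads may have been lost in alignment to a Vitis vinifera reference, or genes are absent or silent in that species, is left open by these values, since neither the reference nor a genome of it was at hand. Such a loss, if the same at both stages, is argued against as the whole source of the differing ripening changes: among 10563 models at 5 CPM or more in both cultivars at both stages, 27.0% were called for the difference.

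E-L 35 lay near E-L 38 in Cabernet Sauvignon and nearer to E-L 34 in Danfeng-2, a gap of 49.7 percentage points on the ripening axis. The libraries that stood apart are argued against as the source, since the gap was 58.8 without them, and depth by the stage before: mean totals were 1.51 times as large in Cabernet Sauvignon at E-L 34, where the gap was 0.2 (3.5 without those libraries, -3.6 on the Danfeng-2 axis), and 1.2 times at E-L 35. Thinning every library to the lowest total, which removed up to 42.8% of its counts, left 100% of the gap; since levels are scaled to library size, this alone is weak evidence. An axis from 1 cultivar gave at least 46.4 at E-L 35. A hypothesis that these values leave open is that skin at E-L 35 may be further along in Cabernet Sauvignon than in Danfeng-2. Ripening in Danfeng-2 may come later relative to that stage mark, or the berries may have been sampled at different points within the stage. The design does not separate these, and neither was tested.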

How the results depend on the processing

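Leaving out the 3 libraries that stood apart, thinning and the axes of single cultivars were chosen after the data were seen. Of 231 counts of calls under alternatives, 215 stayed within 1.5 times the reported count. Without a fold minimum the counts were 10527, 9691, 11314 and 10864 between cultivars at E-L 33, 34, 35 and 38; 8642, 11002, 5732 and 12488 for the steps from E-L 33, 34 and 35 and the whole span in Cabernet Sauvignon; 3824, 4897, 9207 and 10572 in Danfeng-2; and 9201 for the difference, since more models pass without it. limma on log2(FPKM + 1) gave 1218 for E-L 38 against 35 in Cabernet Sauvignon and 1140 for E-L 34 against 33 in Danfeng-2; for the latter a fit of the 2 groups alone gave 939, with 46.6% rather than 32.9% higher (the cause was not tested). Leaving out single libraries moved the count of the difference between 5341 and 6203, and of E-L 34 against 33 in Danfeng-2 between 1503 and 2018. Without the 3 libraries that stood apart the counts were 6182 at E-L 33, 2454 for E-L 35 against 34 in Danfeng-2 and 6618 for the difference, and the gap at E-L 35 was 58.8 points. Counts in the regions, in the 8 comparisons and directions whose scan passed, stayed within 1.5 times in 142 of 142 alternatives; elsewhere they moved, as on chromosome 16 for E-L 35 against 34 in Danfeng-2 (12 rose, 24 without the 3 libraries). Named models kept call and direction in 293 of 296; Grape_newGene_1381 was lost in the fit of 2 groups and with limma on log2(FPKM + 1) (adjusted p 0.14 and 0.064, and 0.0015 at the lowest over its alternatives), and VIT_06s0009g03000 without Danfeng-2 E-L 33 replicate 3 (1.0, and 2.1e-15 at the lowest).

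Deviations of libraries with the same replicate number correlated at 0.0 on average (-0.28 to 0.29, 4 of 84 pairs over 0.1), so the numbers do not pair the libraries. With the replicate number as a replicate block, counts were 5156, 5018, 6289 and 5785 between cultivars, 7518 and 5519 for the spans and 5569 for the difference. The list tests and their alternatives were not run, since no list had a member. DESeq2 gave no value for 4 named models.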

Other observations

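The tests of neighbouring, overlapping and newly predicted models in this part were written down before their results were seen. The concentration of counts is a description without a test.

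Transcripts were concentrated in fewer genes in ripe berries than in green ones, stage by stage in Cabernet Sauvignon and only at E-L 38 in Danfeng-2. In Cabernet Sauvignon 50% of the counts lay in 1045.7 ± 5.5 models at E-L 33, 923.3 ± 71.7 at E-L 34, 768.3 ± 12.3 at E-L 35 and 706.3 ± 6.8 at E-L 38 (SD, n = 3). In Danfeng-2 the number was 1104.7 ± 47.4, 1114.7 ± 14.8 and 1164.3 ± 28.4 at the first stages and 826.7 ± 6.5 at E-L 38. The 10 most abundant models took 6.1% ± 0.1 of the counts at E-L 33, 10.4% ± 0.2 at E-L 35 and 10.8% ± 0.2 at E-L 38 in Cabernet Sauvignon, and 6.4% ± 0.1, 5.6% ± 0.6 and 9.6% ± 0.3 in Danfeng-2.

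Neighbouring models on a chromosome changed in the same direction more often than models in random order. From E-L 33 to E-L 38 in Cabernet Sauvignon, both members of 10.91% of 16646 adjacent pairs were called in the same direction, against a mean of 8.63% and a highest value of 9.31% in 1000 random orders. Overlapping models that share reads may add to this: without them between 64.0% and 86% of the excess remained over the 7 comparisons, which leaves part of it undecided.

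Newly predicted models differed between the species more often than others. At E-L 38, 49.7% of 553 were called, against a mean of 41.1% and a highest value of 49.0% in 10000 draws of reference models matched on mean level. Without such matching, their share also exceeded that of reference models on the steps in Cabernet Sauvignon (24.4% against 18.8%, 32.7% against 31.4% and 17.9% against 10.4%). In Danfeng-2 it was lower on each step (7.4% against 10.4%, 5.8% against 9.2% and 21.7% against 24.4%). A candidate explanation for the difference between the species, not tested further, is that models predicted from these reads may include sequences specific to 1 of the species.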
